A study of Mus musculus with 21 samples.

How the data were processed

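The series holds 21 samples of SCO and hippocampus from C57BL/6 mice. Of these, 9 were sampled on postnatal day 0, 5 from hippocampus and 4 from SCO, and 12 on postnatal day 60, 6 of each tissue. The P60 samples were not analysed here. Per the labels, total RNA was prepared with the RNeasy Micro Kit and libraries with the TruePrep DNA Library Prep Kit. Per the submitters' processing notes, the tools were FastQC for read quality, HISAT and HISAT2, featureCounts and DESeq2, with the build GRCm38. Tool versions, the gene annotation, the strand setting and the handling of reads that match more than one gene are not given in the sources used here.

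The deposited table has 31883 genes by versioned Ensembl identifier. Its per-library values were deposited as a normalized signal: read counts per gene divided by 1 size factor per library, so that libraries of different depth are on one scale. The columns of the authors' own comparison are named as in a DESeq2 results table, per the file headers. They hold the deposited log2 fold change with its standard error, a statistic given as a score, and the deposited p-value and adjusted p-value. The mean of the library columns equals the authors' mean column within a relative 8e-15. A size factor scales every gene of a library alike, so a library whose RNA make-up differs as a whole can shift all of its genes.

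Every value of a library is a whole multiple of what 1 read is worth. Dividing by that step gave whole reads for 100% of values, with a tolerance of 1e-06 and a largest distance of 1.4e-09. The recovered depth is 35379988 to 151009954 reads per library. A gene at 0 in a library is bounded by 3 reads, and intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. The number of columns belonging to samples of another series was 0.

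The design fixed before the data were examined assumed read counts and named an edgeR test for them. Its rule for normalized values was used in place of that test because the table holds normalized values. The main test was limma-trend on log2(value + 1), a pseudocount of 1, for genes with a mean of at least 1 in either tissue, which left 28150 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the 2-fold count also asked for an absolute log2 fold change of at least 1. Fold changes are SCO minus hippocampus on the log2(value + 1) scale, which understates the change of low genes. They exceed the ratio of the means where a tissue with low values holds a few high ones: Nup62cl and Cdhr3 had a mean 61.7 and 19.5 times as high in SCO, and Fezf2 55.6 times as high in hippocampus. No covariate was used. The design did not fix whether the variance moderation should be robust: it was run first with the robust option (825 genes) and then without it (859 genes), and the plain version was taken after the first number had been seen. Marker values, principal components and some alternative counts had also been seen before the added alternatives were chosen.

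Gene lists, 32 in all, were fixed from textbook markers of the SCO, the hippocampus and neighbouring tissues, and tested with camera on the same log2 values in place of the log2 CPM that the design named for counts. The preset correlation was 0.01, a list needed 5 tested members, and p-values were adjusted over the lists. Fry and camera with an estimated correlation were alternatives. Of the lists, 19 have a member at 0 reads in a whole tissue. Setting such members to their bound moved a list median by at most 0.97, to 3.96 for habenular, thalamic and pretectal neurons. That of the midline list became 2.28. The bound is the log2 ratio of the mean in the other tissue to 3 reads per library. The other members keep the difference of mean log2(value + 1). Such medians mix different scales, so a shift can come from the mix alone. Measures per library were compared by a two-sided exact permutation test of the difference of means over all splits of the libraries, adjusted over 7 measures.

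The rule for named genes was fixed beforehand. It takes Sspo, Car3, Spdef, Tmsb4x and Tmsb10. It adds the 10 highest and the 10 lowest called genes by log2 fold change with a mean of at least 20 CPM in the higher tissue and no overlap between the tissues, without predicted gene models and pseudogenes. It adds up to 4 called members of each list with a mean of at least 10 CPM. The text names fewer of the last kind, and some genes that the rule takes are not reported here. Further called list members, and Ttr, were named after their values were seen.

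Gene positions come from the GENCODE M21 annotation of GRCm38, used where the versioned identifier matched (31302 of 31883 genes; 31809 match without the version). Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9. The tests were checked on simulated counts drawn from the means and depths of these libraries, with 50 genes changed at each of 4 fold sizes. In the simulated comparison of SCO and hippocampus, limma-trend over 26912 genes recovered 3 of 50 genes at 2-fold, 28 at 4-fold, 44 at 16-fold and 49 at 256-fold, and 8 of its 132 calls were unchanged genes. DESeq2, over 19521 genes, called 255 of which 104 were unchanged, and edgeR 127 of which 5 were unchanged. A simulated 4-fold shift of a list was recovered, and 0 of the lists that share no gene with it were called. Genes were drawn independently there, so the simulation cannot show how often camera calls lists of correlated genes. The list of cytosolic ribosomal proteins, for 1, had an estimated correlation of 0.84.

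Alternatives fixed beforehand were edgeR with DESeq2 size factors, upper quartile factors or library size, DESeq2, limma-voom with sample weights, other filters and pseudocounts, replicate numbers as blocks, and each replicate left out in turn. Alternatives chosen after seeing the data were the planned edgeR test itself with TMM on the recovered reads, other scalings, filters, robust moderation and thinning of reads within limma-trend, sex as a covariate, and SCO replicate 4 with hippocampus replicate 2 left out.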

Results

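The transcriptome of the mouse subcommissural organ (SCO), a small secretory gland of ependymal cells in the roof of the third ventricle, was compared with that of the hippocampus on postnatal day 0 (P0). Bulk RNA sequencing values were held for 9 libraries from C57BL/6 mice, 5 from hippocampus and 4 from SCO. The recovered depth of the hippocampus libraries was 43401688, 36787949, 53450314, 151009954 and 143312271 reads for replicates 1 to 5. The SCO libraries held 35379988, 36243591, 64242533 and 50568787 reads for replicates 1 to 4. The 12 samples of postnatal day 60 were not analysed here. Values per gene are read counts divided by a size factor per library, called normalized counts here. The labels do not say whether the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

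The comparison asked which genes set the newborn SCO apart from the hippocampus. Sspo, which encodes SCO-spondin, the large glycoprotein of the Reissner fibre, had a mean of 4312 ± 3627 normalized counts (SD, n = 4) in SCO and 1.56 ± 0.975 (SD, n = 5) in hippocampus. Its log2 fold change was 10.48 (SE 0.80, limma adjusted p = 0.000175), and SCO replicate 2 held the highest value, 9720. Spdef, an ETS transcription factor of secretory epithelia, rose by 9.57 on the log2 scale (SE 1.45, limma adjusted p = 0.00594), from 64.3 ± 105 to 10250 ± 4315. Of the hippocampus libraries, replicate 2 held the most Spdef, 244. Car3, a carbonic anhydrase, rose by 4.58 (SE 0.71, limma adjusted p = 0.00659), from 174 ± 133 to 3258 ± 1309. The interneuron transcription factor gene Dlx1 showed the opposite pattern, with 2835 ± 1003 normalized counts in hippocampus and 0 reads in all 4 SCO libraries.

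Of 28150 genes tested, 859 passed an adjusted p of 0.05 in limma-trend, 481 higher and 378 lower in SCO. Of these, 839 differed at least 2-fold on the log2(value + 1) scale, 471 higher and 368 lower. The normalized counts of the tissues did not overlap for 850 of the 859 genes. Among all tested genes 8.53% had no overlap, against 1.59% by chance. The number called was 565 without hippocampus replicate 1, 498 without hippocampus replicate 3 and 564 without SCO replicate 3. It was 986 without SCO replicate 4 and hippocampus replicate 2, a pair chosen after the data were seen.

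The 10 genes that stood highest in SCO by the naming rule were Ldlrad2, Mab21l2, Pax3, Esm1, Spp2, Sspo, Pamr1, Npsr1, Gata3 and Nup62cl, with log2 fold changes from 11.94 down to 9.98. Ldlrad2 had a mean of 6676 ± 2106 normalized counts in SCO and 0.786 ± 0.751 in hippocampus (log2 fold change 11.94, SE 0.75, limma adjusted p = 6.17e-05). Mab21l2, a developmental regulator of the eye and midbrain, reached 9652 ± 2635 in SCO. Pax3, a transcription factor of the dorsal neural tube, had 2696 ± 690 normalized counts in SCO and 0 reads in all 5 hippocampus libraries, which makes it at least 961-fold higher. Esm1, an endothelial proteoglycan gene, also had 0 reads in hippocampus and was at least 1000-fold higher in SCO, where replicate 1 held 7326 and the other replicates between 840 and 1635. These bounds use a floor of 3 reads per library, a mean of 2.81 normalized counts in hippocampus, and cover counting error only. Spp2, a secreted phosphoprotein gene, had 3927 ± 1170 in SCO and 1.19 ± 0.941 in hippocampus. Npsr1, the neuropeptide S receptor gene, had 3948 ± 1838 against 17.3 ± 36.5.

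Among the genes that stood lowest in SCO were Dlx1, Lhx6, Fezf2, Sertm1, Chrm1, Bhlhe22, Tbr1, Cdh9 and Tbata, with log2 fold changes from -11.38 to -8.55. Dlx1, without a read in SCO, was at least 756-fold lower there. The floor of 3 reads per library is a mean of 3.75 normalized counts there. Lhx6, a regulator of cortical interneurons, had 4199 ± 1380 in hippocampus and 5.59 ± 9.31 in SCO. Fezf2, a regulator of subcortically projecting neurons, had 4621 ± 1105 in hippocampus. In SCO, Fezf2 had 0 in 3 libraries and 332 in replicate 4. Chrm1, the M1 muscarinic receptor gene, had 1201 ± 988 in hippocampus and 1 read in the 4 SCO libraries together.

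**Figure D1:**
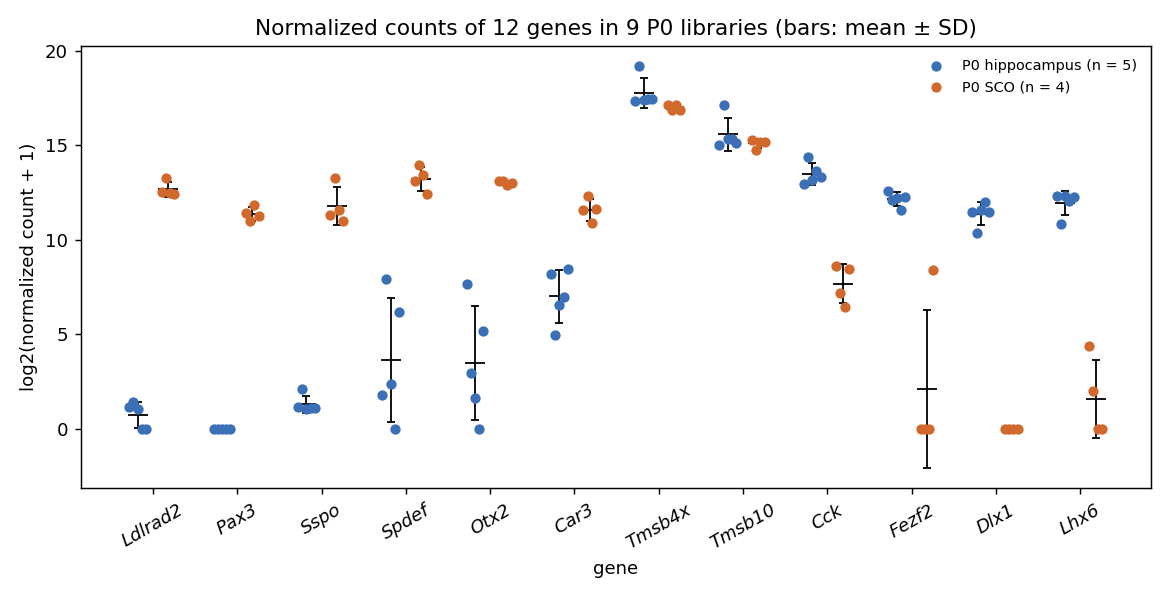
Log2(normalized count + 1) of 12 genes in each of the 5 hippocampus (blue) and 4 SCO (orange) libraries at P0, with one point per library and black bars for the mean ± SD of the plotted values. Ldlrad2, Pax3, Sspo, Spdef, Otx2 and Car3 are higher in every SCO library than in any hippocampus library, and Cck, Fezf2, Dlx1, Lhx6 and Tmsb4x lower. Tmsb10 overlaps between the tissues, and Tmsb4x and Tmsb10 stand highest in hippocampus replicate 2.

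In the genome build GRCm38, Sspo (ENSMUSG00000029797.13) lies on the plus strand of chromosome 6 from 48448229 to 48501250. Spdef (ENSMUSG00000024215.14) lies on the minus strand of chromosome 17 from 27714352 to 27728955, and Car3 (ENSMUSG00000027559.5) on the plus strand of chromosome 3 from 14863512 to 14872523. Pax3 (ENSMUSG00000004872.15) lies on the minus strand of chromosome 1 from 78101267 to 78197134. Each is an annotated gene whose reads were summed over the gene, so exons and introns are not resolved. Reads of Otx2 and Dlx1 cannot be told from those of the antisense genes annotated beside them, because the strand setting of the counting is not given in the sources used here.

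Gene lists fixed beforehand were compared with the other genes by camera. Of the 32 lists, 22 passed an adjusted p of 0.05, 15 higher and 7 lower in SCO. Of the 22, 12 also passed with an estimated correlation between genes. Among the 10 tested genes known from the literature to mark the SCO, 4 rose (Sspo, Spdef, Car3 and Pax6), 6 when adjusted over the list alone, and 0 fell. The list passed camera at adjusted p = 5.42e-07. Pax6, a transcription factor of the dorsal forebrain, rose by 2.75 on the log2 scale (SE 0.37, limma adjusted p = 0.0032).

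Genes of motile cilia and ependymal cells were higher in SCO: 21 of 57 rose, 36 when adjusted over the list alone, and 0 fell (camera adjusted p = 6.62e-22). Rsph4a, a radial spoke component, rose by 8.64 (SE 1.72, limma adjusted p = 0.0245), a call that ends in 5 of the 9 left-out replicates and in edgeR (adjusted p 0.0921 to 0.116). Cfap52, a cilia and flagella associated gene, had 7222 ± 1417 normalized counts in SCO and 551 ± 302 in hippocampus (log2 fold change 3.88, SE 0.45, limma adjusted p = 0.00126). The cadherin family genes Cdhr3 and Cdhr4 rose by 7.54 and 8.50. The Cdhr3 call (limma adjusted p = 0.0452) ends in 8 of the 9 left-out replicates and in edgeR (adjusted p 0.227 to 0.250). Of 30 genes of dorsal midline and roof plate patterning, 6 rose, among them Pax3, Otx2, Zic4, Fgf15 and Zic1, and Msx3 fell, 12 and 1 when adjusted over the list alone (camera adjusted p = 2.08e-05). The Fgf15 call ends in 4 of the 9 left-out replicates and in edgeR (adjusted p 0.113 to 0.127). That of Zic1 also ends in 4 of the 9 left-out replicates (adjusted p at most 0.0692). Otx2, a homeobox gene of the diencephalon and midbrain, had 8287 ± 480 normalized counts in SCO and 48.1 ± 84.5 in hippocampus. Zic4, a zinc finger gene of the dorsal midline, had 25660 ± 4664 against 210 ± 253.

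Markers of habenular, thalamic and pretectal neurons were higher in SCO, with 17 of 46 up and 0 down (camera adjusted p = 4.18e-15). Adjusted over the list alone, 23 rose and 4 fell. The genes included Gata3 (log2 fold change 10.05), Tfap2b (9.97), Otx2 (9.55) and Zic4 (8.76), of which Otx2 and Zic4 are also in the midline list. Gata3 and Tfap2b encode transcription factors found in neurons of the pretectum and midbrain, among other tissues. Over the SCO libraries Gata3 ranged from 1113 to 8755 normalized counts, and Otx2 from 7705 to 8708. Bulk values cannot tell whether the genes of this list were read from SCO cells or from neighbouring neurons in the samples. In the list of protein secretion and folding in the endoplasmic reticulum, 4 of 78 members rose and 1 fell, 7 and 1 when adjusted over the list alone (camera adjusted p = 7.39e-05). Kdelr3, a retrieval receptor for resident proteins of the endoplasmic reticulum, rose by 3.45 (SE 0.43, limma adjusted p = 0.00188). The chaperone gene Hsp90b1 rose by 1.32 and the nucleotide exchange factor gene Sil1 by 1.37. The Sil1 call ends in 2 of the 9 left-out replicates (adjusted p 0.0538 to 0.0565). The signal peptidase subunit gene Sec11c fell by 1.31, a call that 8 of the 9 left-out replicates end (adjusted p 0.0534 to 0.0926).

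Hippocampal and cortical excitatory neuron genes were lower in SCO: 20 of 36 fell, 29 when adjusted over the list alone (camera adjusted p = 1.43e-23). The member that rose was Slc17a6, the vesicular glutamate transporter gene typical of the diencephalon, at 2.63 on the log2 scale. 3 members rose when adjusted over the list alone. Bhlhe22 and Tbr1, transcription factor genes of cortical and hippocampal projection neurons, had log2 fold changes of -9.42 (SE 0.98) and -9.27 (SE 1.01). Of 22 genes of GABAergic interneurons, 6 fell and Calb2 rose, 8 and 1 when adjusted over the list alone (camera adjusted p = 2.08e-05). Of 39 pan-neuronal and synaptic genes, 10 fell and 0 rose, 18 fell when adjusted over the list alone (camera adjusted p = 8.44e-11). The adjusted p of that list was 0.0554 with an estimated correlation. The NMDA receptor subunit gene Grin2b fell by 2.63. Nrgn, a postsynaptic calmodulin-binding protein gene, fell by 3.17.

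**Figure D2:**
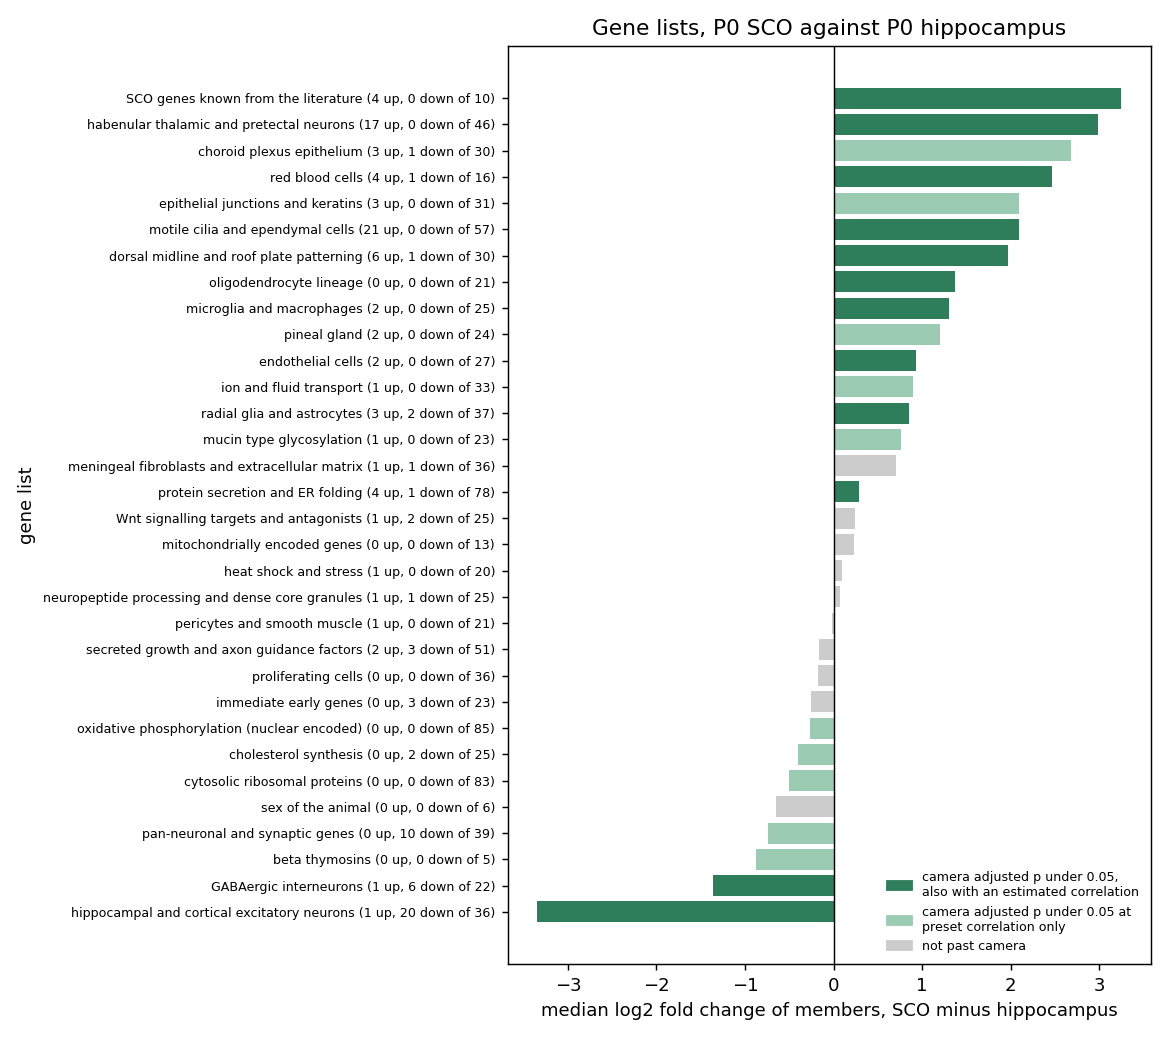
Median log2 fold change (SCO minus hippocampus, horizontal axis) of the tested members of each of 32 gene lists, with the number of members that passed limma-trend in each direction beside the name. Dark green bars passed camera with the preset and the estimated correlation, light green bars with the preset correlation only and grey bars with neither. The excitatory neuron list stands lowest at -3.35 and the list of SCO genes highest at 3.25. With members at 0 reads set to their bound the habenular, thalamic and pretectal list had 3.96. That median mixes different scales and cannot be ranked against the plotted ones.

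Glial, endothelial and blood genes were higher in SCO as groups. Of 37 radial glia and astrocyte genes, 3 rose (Ttyh1, Vim and Sparc) and 2 fell (Slc1a2 and Ncan), 13 and 4 when adjusted over the list alone (camera adjusted p = 7.39e-05). The Ncan call ends in 6 of the 9 left-out replicates (adjusted p 0.0593 to 0.0739) and that of Sparc in 5. Vim, an intermediate filament gene of radial glia and ependyma, rose by 1.88 (SE 0.27, limma adjusted p = 0.00464). Slc1a2, the main glutamate transporter gene of astrocytes, fell by 1.79 (SE 0.30, limma adjusted p = 0.00993). Of 21 oligodendrocyte lineage genes 0 were called over all genes, 6 rose when adjusted over the list alone, and the list passed camera (adjusted p = 6.46e-05). Of 25 microglia and macrophage genes, 2 rose, among them the lysosomal protease gene Ctss, and 11 rose when adjusted over the list alone (camera adjusted p = 3e-07). Of 27 endothelial genes, Esm1 and Eng rose, 5 when adjusted over the list alone (camera adjusted p = 0.000122). Of 16 red blood cell genes, 4 rose (Hbb-bs, Hba-a1, Hbb-bt and Alas2) and 1 fell, 7 and 1 when adjusted over the list alone (camera adjusted p = 8.76e-06). The Alas2 call ends in 5 of the 9 left-out replicates (adjusted p 0.0715 to 0.0909). Those of Hbb-bt and Hba-a1 end in 4 each (adjusted p at most 0.0674 and 0.0809). Hbb-bs and Hbb-bt are near-identical copies, as are Hba-a1 and Hba-a2, so the division of reads within each pair is uncertain.

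Markers of tissues next to the SCO were also measured in each library. Choroid plexus genes took 0.229% ± 0.190 of reads in SCO (SD, n = 4) and 0.0653% ± 0.0108 in hippocampus (n = 5), and haemoglobin genes 0.114% ± 0.0296 and 0.0238% ± 0.0150. Both differed in a two-sided exact permutation test over all splits (p = 0.00794, the smallest the design can give, adjusted p = 0.0278 over 7 measures, higher in 4 of 4 SCO libraries than in any hippocampus library). With any replicate left out neither share passed (adjusted p 0.0625 to 0.1), and such splits allow no exact p under 0.0179. In SCO replicate 4 the choroid plexus share was 0.514%, and without that library the difference between the tissues was 0.0691 percentage points instead of 0.164. Ttr, a member of that list, had 2133, 12990, 2.06, 0 and 7234 normalized counts in hippocampus replicates 1 to 5, above SCO replicates 1 to 3 (559, 403 and 108) in 3 of them. Meningeal genes took 0.0533% ± 0.0152 and 0.0270% ± 0.00983 (exact p = 0.0317, adjusted p = 0.0740). Of 30 choroid plexus genes, 3 rose (Abca4, Calml4 and Slc39a12) and Slc5a5 fell, 8 and 2 when adjusted over the list alone (camera adjusted p = 8.41e-06). The Slc5a5 call ends in 8 of the 9 left-out replicates (adjusted p at most 0.0934). The adjusted p of that list was 0.0589 with an estimated correlation.

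Some smaller lists were higher in SCO at the preset correlation only. Among epithelial junction and keratin genes, 3 of 31 rose (Krt18, Prom1 and Cldn10), 5 when adjusted over the list alone (camera adjusted p = 0.000318, adjusted p = 0.0661 with an estimated correlation). Krt18, a keratin of simple epithelia, had 0 reads in hippocampus and was at least 221-fold higher in SCO, with 1875 in replicate 2 and between 169 and 261 in the other replicates. In the list of ion and fluid transport, Car3 rose, 1 of 33 also when adjusted over the list alone (camera adjusted p = 0.00321, adjusted p = 0.163 with an estimated correlation). Without SCO replicate 4 the transport list did not pass (adjusted p = 0.105). In the list of mucin type glycosylation, Spdef rose, 1 of 23, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0170, adjusted p = 0.0730 with an estimated correlation). Of 24 pineal gland genes, Otx2 and Lhx9 rose, 3 when adjusted over the list alone (camera adjusted p = 0.0355, adjusted p = 0.189 with an estimated correlation). The pineal list did not pass without hippocampus replicate 4 (adjusted p = 0.0565), hippocampus replicate 5 (0.0652) or SCO replicate 1 (0.245).

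The beta thymosin genes Tmsb4x and Tmsb10, which encode small actin-binding peptides, did not pass the test in either direction. Tmsb4x had 131700 ± 12970 normalized counts in SCO (SD, n = 4) and 257300 ± 188800 in hippocampus (n = 5), a log2 fold change of -0.75 (SE 0.35, limma adjusted p = 0.330). Tmsb10 had 35400 ± 5261 and 57850 ± 46160 (log2 fold change -0.46, SE 0.39, limma adjusted p = 0.600). The SCO libraries held 120300 to 144200 of Tmsb4x, each below every hippocampus library. Hippocampus replicate 2 held 594800 of it, and the other hippocampus libraries between 164400 and 178700. Without that library Tmsb4x was lower in SCO (log2 fold change -0.40, SE 0.08, limma adjusted p = 0.0239), while Tmsb10 hardly differed (log2 fold change -0.08, SE 0.14, limma adjusted p = 0.784). Of the 5 beta thymosins tested, 0 passed over all genes and 2 were lower when adjusted over the list alone. The list passed camera downward (adjusted p = 0.00432), with adjusted p = 0.328 with an estimated correlation.

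Housekeeping lists were lower in SCO by small amounts at the preset correlation. Of 83 cytosolic ribosomal protein genes 0 were called, also when adjusted over the list alone, with a median log2 fold change of -0.51 (camera adjusted p = 1.38e-08, adjusted p = 0.510 with an estimated correlation). The mean of that list went from -0.49 to -0.19 without hippocampus replicate 2, and it still passed camera. Of 85 nuclear genes of oxidative phosphorylation 0 were called, also when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.00623, adjusted p = 0.712 with an estimated correlation). The oxidative phosphorylation list did not pass without hippocampus replicate 2 (adjusted p = 0.568) or SCO replicate 2 (adjusted p = 0.0938). Of 25 cholesterol synthesis genes, Fdft1 fell by 1.19 (SE 0.17) and Fdps fell by 1.10 (SE 0.24), also when adjusted over the list alone (camera adjusted p = 0.00183, adjusted p = 0.0650 with an estimated correlation). The Fdps call ends in 6 of the 9 left-out replicates (adjusted p 0.0537 to 0.101) and with 1 edgeR scaling. Fdft1 encodes squalene synthase and Fdps the enzyme that makes farnesyl diphosphate.

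Genes of secreted growth and guidance factors moved both ways. Of 51 tested, Ptn and Slit2 rose and Slit3, Tgfb2 and Reln fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.632). Ptn, the pleiotrophin gene, rose by 2.56 (SE 0.21, limma adjusted p = 0.000202), from 32380 ± 5252 to 195200 ± 56470. Reln, the reelin gene of Cajal-Retzius cells, fell by 2.30 (SE 0.33, limma adjusted p = 0.00443), and Tgfb2 by 2.95. Of 25 neuropeptide and dense core granule genes, Tac1 rose by 3.22 and Cck fell by 5.81, 2 and 2 when adjusted over the list alone (camera adjusted p = 0.777). Cck had 12190 ± 5457 normalized counts in hippocampus and 240 ± 147 in SCO. Of 25 Wnt targets and antagonists, Notum rose and Sfrp1 and Ccnd2 fell, 2 and 3 when adjusted over the list alone (camera adjusted p = 0.717). The Notum call ends in 6 of the 9 left-out replicates (adjusted p at most 0.0738), and Notum lies below the filter of edgeR. The Tac1 call ends in 6 of the 9 left-out replicates (adjusted p 0.0639 to 0.0758). The Sfrp1 call (limma adjusted p = 0.0427) ends in 8 of the 9 left-out replicates and in edgeR (adjusted p 0.450 to 0.476). Of 23 immediate early genes, Egr3, Fosl2 and Nr4a3 fell, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.263, fry adjusted p = 0.0348 and lower). The Fosl2 call ends in edgeR (adjusted p 0.0575 to 0.0613).

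The remaining lists did not pass camera. Cdkn1a, a cell cycle inhibitor gene, rose by 2.45 (SE 0.34, limma adjusted p = 0.0036) among 20 heat shock and stress genes, of which 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.264). Vtn, the vitronectin gene, rose among 21 pericyte and smooth muscle genes, also when adjusted over the list alone (camera adjusted p = 0.634). The median of that list was -0.02 and its mean 0.01. Among 36 meningeal genes Ptgds rose and Col12a1 fell, 2 and 1 when adjusted over the list alone (camera adjusted p = 0.462, adjusted p = 0.0494 without SCO replicate 3). The Ptgds call ends in 7 of the 9 left-out replicates (adjusted p 0.0710 to 0.111), and that of Vtn in 6 (0.0520 to 0.0931). Of 36 genes of proliferating cells 0 were called, also when adjusted over the list alone (camera adjusted p = 0.299, adjusted p = 0.0174 and lower without hippocampus replicate 2). Of 13 mitochondrially encoded genes 0 were called, also when adjusted over the list alone (camera adjusted p = 0.0958, adjusted p = 2.25e-05 and higher without hippocampus replicate 2). Of 6 sex-linked genes 0 were called, also when adjusted over the list alone (camera adjusted p = 0.807). At an unadjusted p under 0.05, 4354 of all tested genes passed in limma-trend, and edgeR called 682 at an adjusted p of 0.05.

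The libraries grouped by tissue. Pearson correlations across genes, which are not independent replicates, lay between 0.824 and 0.871 within hippocampus, between 0.813 and 0.828 within SCO and between 0.768 and 0.816 across tissues. The first principal component held 22.5% of the variance and placed the hippocampus libraries from -170 to -99.9 and the SCO libraries from 128 to 205. Depth, genes detected, the share of the 10 most abundant genes and the mitochondrial share did not differ between the tissues past the exact test, with adjusted p of 0.455, 0.167, 0.518 and 0.548. The mitochondrial share was 1.95% in hippocampus replicate 2 and between 0.838% and 1.03% in the other hippocampus libraries. Without that library it was higher in every SCO library (1.06% to 1.58%) than in any hippocampus library, with the smallest exact p that 4 against 4 allow (0.0286, adjusted p = 0.0667).

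The authors' deposited table lists 2721 genes with an adjusted p under 0.05, 1499 higher and 1222 lower in SCO, of 21475 genes with an adjusted p. Of the 859 genes called here, 825 are among the 2721 of the authors' deposited table with the same direction, and 0 with the opposite direction. For Sspo the authors' deposited table gives a log2 fold change of 11.61 with a standard error of 0.75, and for Tmsb4x -0.97 with 0.43 and an adjusted p of 0.138. Its log2 fold changes are smaller than those here for Spdef (7.32), Rsph4a (6.02), Fezf2 (-5.80, adjusted p = 0.0477), Nup62cl (5.95, adjusted p = 0.0511) and Sfrp1 (-3.33, adjusted p = 0.252).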

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

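All tests weighed here were chosen after the result was seen except the splits of the libraries and the test of transcript length. Within each tissue, the highest and the lowest library were set against the others for each named gene and library measure by Dixon's criterion at 95%. The values were not log-transformed, so a long upper tail makes the highest library stand apart more easily. Some groups would also pass at 95% by chance. Of 152 groups of values 37 had a library that stood apart. In 9 of these every other library of the tissue had 0 reads, where any read meets the criterion, and 8 of the 9 lie in SCO replicate 4. Hippocampus replicate 2 stood apart 12 times and SCO replicate 4 10 times.

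Ttr, the transthyretin gene and the most abundant transcript of the choroid plexus, had 171300 normalized counts in SCO replicate 4 and 559, 403 and 108 in the other SCO libraries, far from the rest of its group, as was the choroid plexus share of 0.514%. Choroid plexus tissue in that dissection may account for it but stays open. Of 27 other choroid plexus genes with a mean of at least 100 over all SCO libraries, 16 were highest in replicate 4. Chance gives 1 in 4 (exact binomial p = 0.000162), but replicate 4 itself helped to choose these genes. Chosen by their hippocampus values, 14 of 26 were highest there (exact binomial p = 0.00209). Chosen by the other SCO libraries alone, 8 of 19 were highest there (exact binomial p = 0.108). That choice leaves out genes that are low in the other SCO libraries, such as Kcnj13. It can therefore miss an excess of genes particular to choroid plexus. These p-values do not measure evidence from independent samples, since they count genes within SCO replicate 4, which are not independent. Enpp2 had 49100 there and Kcnj13 2835, against means of 15670 and 86.6 in the other SCO libraries, but Calml4 and Slc39a12, which SCO also expresses, were not highest there. The tables argue against a larger share of SCO cells, since 9 genes of the SCO list had a median difference of -1.04 there. Of the 9, 7 were lower there, and the SE of their mean, taken over genes, was 0.54. Variation between animals in the SCO itself was not tested.

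Tmsb4x and Tmsb10 stood apart in hippocampus replicate 2, with 594800 and 140200 normalized counts, 3.44 and 3.76 times the mean of the other hippocampus libraries, as did the mitochondrial share of 1.95%. An excess of short transcripts in that library may contribute to the high thymosin counts. Over 14423 other protein-coding genes, the 25% with the shortest transcripts exceeded the 25% with the longest by a median log2 difference of 0.775 there. It was at most 0.232 in the other 8 libraries. On the log2 scale Tmsb4x and Tmsb10 stood 1.78 and 1.92 above the other hippocampus libraries, more than that difference. Ribosomal protein genes were 1.56 higher there and genes of oxidative phosphorylation 1.64. The tables argue against low depth as the cause, since SCO replicate 1, with 35379988 reads, had Tmsb4x only 0.146 above the rest of its group on the log2 scale, the higher of the 2 other libraries of such depth. Whether RNA quality or the animal's biology underlies the excess stays open.

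Haemoglobin transcripts took 0.114% of reads in SCO and 0.0238% in hippocampus. More red blood cells in the SCO samples may account for it but stay open: 8 of 8 other erythroid genes had a higher log2 mean in SCO (median log2 fold change 2.35, exact binomial p = 0.00781), but the 5 with a mean of at least 1 in both tissues had a median of only 0.741 (p = 0.0625), and Alas2 alone passed limma-trend. The tables argue only weakly against more blood vessel tissue alone. The endothelial list had a median log2 fold change of 0.926, below 1.95, the lowest haemoglobin change less its SE. Its bootstrap 95% interval, 0.540 to 1.58, was drawn over genes and leaves out the spread between libraries. The binomial tests of erythroid genes also count genes, which are not independent. A richer blood supply of the SCO, a difference that the tissues themselves could bring, stays open and untested.

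Among splits of the libraries the real grouping gave the most genes, but such splits cannot exclude chance. Every other split has both tissues in at least 1 group, which widens the spread within that group and by itself lowers the count. Of 100 splits into 4 and 5 libraries, the real one included, 1 gave as many as 859 genes and the highest of the others gave 59. For the 839 genes of at least 2-fold it was also 1, with 59 as the highest other. For the 22 gene lists it was 2, with 22 as the highest other, in a split that differs from the real one only in placing hippocampus replicate 2 with the SCO libraries. Splits with both tissues in the group of 4 gave up to 21 lists, and the median of the other splits was 6. The number of lists thus sets the real grouping apart less than the number of genes does.

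The other libraries that stood apart are given as values. In hippocampus replicate 2, Cplx2 stood highest at 11190, Grin2b at 24320, Nup62cl at 368, Rsph4a at 287, Spdef at 244, Npsr1 at 82.5, Gata3 at 14.9 and Sspo at 3.30, and Lhx6 lowest at 1821. In SCO replicate 4, Fezf2 stood highest at 332, Sfrp1 at 307, Fosl2 at 23.5, Cdh9 at 17.9, Tbr1 at 12.3, Sertm1 at 5.60, and Bhlhe22 and Chrm1 at 1.12 each, the worth of 1 read. In hippocampus replicate 5, Cdhr3 was highest at 761, Fgf15 at 426 and Ttyh1 at 2648. In hippocampus replicate 1, Otx2 was highest at 197, Pamr1 at 161 and Pax6 at 1873, and in hippocampus replicate 4 Sfrp1 at 1796. In SCO replicate 1, Esm1 was highest at 7326, Lhx9 at 5935, Tbata at 65.7 and Lhx6 at 19.4. In SCO replicate 2, Sspo was highest at 9720, Ldlrad2 at 9819, Krt18 at 1875 and Dlx5 at 332.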

How the results depend on the processing

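Alternatives within limma-trend, other than the planned pseudocounts, filter, blocks and left-out replicates, and edgeR with TMM on the recovered reads were chosen after the data were seen. No called gene changed sign under any alternative run. The 859 genes became 1944 with DESeq2 and 1623 with limma-voom, of which 1720 and 1444 at least 2-fold, against 839. In simulated data 104 of the 255 genes that DESeq2 called were unchanged. Genes were drawn independently there and only 50 were changed at each fold size. The simulation therefore cannot show how many of the 1944 calls are false. The 859 and 839 genes became 478 and 471 with edgeR without a low-count filter. With TMM and its filter edgeR called 682, and limma-trend without a filter called 710. The cause of these differences was not tested. Leaving out each replicate in turn gave 498 to 1077 genes, and 495 to 960 at least 2-fold. Of 68 called named genes, 17 lost their call without at least 1 of the replicates and kept their direction: Alas2, Cdhr3, Dlx5, Fdps, Fgf15, Hbb-bt, Lhx9, Ncan, Prom1, Ptgds, Rsph4a, Sec11c, Sfrp1, Sil1, Slit3, Tac1 and Vtn (adjusted p 0.0504 to 0.118). Of 119 called list members, 40 lost their call without at least 1 of the replicates and 14 in edgeR with TMM. Among the genes that stood highest and lowest, Nup62cl, Pamr1, Fezf2 and Tbata were not called by edgeR. With upper quartile factors the median log2 fold change of all genes is -0.14, against -0.03, and 50.2% of the calls are higher, against 56%. The 22 lists became 12 with an estimated correlation and ranged from 21 to 23 with a replicate left out. Fry called 20 lists, of which 18 are among the 22. The beta thymosin, transport, ribosomal protein and oxidative phosphorylation lists did not pass fry (adjusted p 0.1, 0.0615, 0.276 and 0.547). The immediate early and the heat shock list passed fry only (adjusted p 0.0348 and 0.0461). Over all alternatives, 295 values of named genes, 26 of lists and 18 of library measures lost significance with their direction kept, and 1, 6 and 0 became significant. The 18 are the haemoglobin and choroid plexus shares with each replicate left out.

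Titles number the replicates 1 to 4 in both tissues, and brackets share the numbers 3 and 6. Deviations of same-numbered libraries had correlations between -0.0289 and 0.0569, the highest for 2 libraries with the same bracket number. They give no clear sign of pairing, since not every library correlated best with its own number. The title numbers 3 and 4 each join libraries of opposite sex by Xist and Y-linked genes, so those pairs are not of 1 animal. The libraries that share bracket number 3 are both female and those that share 6 both male, so a shared animal stays open there. With the title number as a replicate block 1 gene was called, 1 of them at least 2-fold, and with the bracket number 0 and 0 (unadjusted p under 0.05: 3640 and 2050 genes in limma-trend). These fits leave few residual degrees of freedom. The lists past camera were 21 and 19.

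Lists that did not pass camera in the main test changed direction as follows, by mean log2 fold change. The neuropeptide list had 0.0664 in fry, which takes it downward, -0.111 with SCO replicate 4 and hippocampus replicate 2 left out, and -0.162 to 0.427 with a replicate left out. The Wnt list had -0.0944 with the stricter filter, -0.674 with the bracket block and -0.102 to 0.405 with a replicate left out. The pericyte list had -0.128 to 0.250 with a replicate left out, with the same direction in camera throughout. With the bracket block the proliferating list had 0.287, the meningeal list -0.788 and the mitochondrial list -0.213. The sex-linked list had -0.0765 with the title block and -1.37 to 0.151 with a replicate left out. The oxidative phosphorylation list, called in the main test, had -0.0299 with those 2 libraries left out and -0.375 to -0.00797 with a replicate left out, where camera read the values nearest 0 as upward relative to all genes.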

Other observations

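The tests and values below were chosen after the data had been seen. Gene families defined by the first letters of their symbols were tested for enrichment among the called genes by a one-sided Fisher's exact test against 16079 tested protein-coding genes, with a minimum of 8 members and p-values adjusted over both directions. Of 305 families, the Cfap genes, which encode cilia and flagella associated proteins, were enriched among the genes higher in SCO, with 7 of 33 members (Cfap126, Cfap161, Cfap206, Cfap299, Cfap45, Cfap52 and Cfap69; adjusted p = 0.00548). The families enriched among the genes lower in SCO numbered 0.

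Genes from outside the lists also stood apart. Il33, an alarmin cytokine gene, rose by 9.25 on the log2 scale in SCO, and Drd1, a dopamine receptor gene, by 7.65. Rbp4, a retinol carrier gene, rose by 7.95, and Hdc, the gene of the histamine-forming enzyme, by 4.12. Wls, a gene needed for Wnt secretion, rose by 3.56. In the other direction Epha4, an axon guidance receptor gene, fell by 6.54. Members of the lists also differed between libraries or tissues. Neurod6, a transcription factor gene of cortical projection neurons, had a log2 fold change of -8.05 (limma adjusted p = 0.0347). Its call ends in 5 of the 9 left-out replicates (adjusted p at most 0.0788). Pou4f1, a habenular transcription factor gene, had 4504 and 2955 normalized counts in SCO replicates 1 and 2, 0 in replicate 3 and 114 in replicate 4. Tph1, the serotonin synthesis gene of the pineal gland, had 4962 in SCO replicate 1 and at most 0.913 in the other SCO libraries.

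Genes that are well expressed in the rest of a tissue were more often without a read in single SCO libraries. Among protein-coding genes with a mean of at least 500 normalized counts in the other libraries of the tissue, 121, 73, 86 and 86 had 0 reads in SCO replicates 1 to 4, and 7, 20, 4, 7 and 41 in hippocampus replicates 1 to 5. The means were 91.5 ± 20.6 (SD, n = 4) and 15.8 ± 15.4 (n = 5), with an exact two-sided permutation p of 0.00794, the smallest this design can give. That mean rests on 3 other libraries in SCO and 4 in hippocampus, which favours SCO. With 3 in both tissues the hippocampus mean was 18.8 ± 15.2 (exact p = 0.00794). Asking for 500 in each of the 3, the means were 15.5 ± 4.36 and 3.15 ± 4.75 (exact p = 0.0238).

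Xist and Y-linked genes give the sex of the animals, which the labels do not state. Xist lay between 4508 and 22700 normalized counts in 6 libraries and between 0.761 and 9.14 in hippocampus replicates 4 and 5 and SCO replicate 3. Ddx3y lay between 3767 and 5372 in those 3 libraries and at most 4.48 in the other 6. In SCO replicate 4, where Xist was 5189 and Ddx3y 1.12, the Y-linked genes together held 254.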
